A study of Mus musculus with 10 samples.

How the data were processed

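RNA of J1 mouse embryonic stem cells, grown without feeder cells per the labels' protocols, was fragmented and precipitated with an m6A antibody. Libraries of the precipitated (IP) and unprecipitated (input) RNA were made with a dUTP method that keeps the strand, per the labels' protocols. The 10 libraries were 1 first input and 1 first IP, 2 WT inputs, 2 WT IPs, 2 Mettl3 KO inputs and 2 Mettl3 KO IPs, and each was placed in its group by its title in the labels. The titles name a genotype only for KO, and the numbered replicates without one were taken as WT. Reads were aligned with TopHat 1.1.3 to the mouse build mm9, per the submitters' processing notes. Read filters, the gene model, the counting of reads with several positions and whether coverage was kept per strand are not given in the sources used here. Overlapping genes, antisense genes and close copies are therefore uncertain.

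For each IP and input pair the deposited window files give coverage, a signal that is never negative, for each exon window, per the file headers. They give the median of this coverage over the gene and a log2 score, called winscore per the file headers. The authors' log2 winscore was checked by recomputing it: log2 of ((IP window + 1)/(IP gene median + 1)) over ((input window + 1)/(input gene median + 1)) gave the deposited value in all 1510223 windows to within 5e-14. Coverage was scaled by the authors with 1 factor per library that is not stated. All low values were whole multiples of a step per library (tolerance 0.001), and total coverage divided by this step gave relative depth. Absolute read numbers were not derived. A window held a median of 48.9 bases of exon in 2878 single-exon genes with a length in the RefSeq table of GRCm38.p6, and the window width is not stated. This table was used only for names and neighbours: 21496 of the 30419 gene names equal a current symbol and 1699 only an older one. Other names were kept as in the files. The files give no coordinates, so regions are named by gene and exon.

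A deposited table gives RPKM values per gene for columns labelled as the 5 inputs, per the file headers. The denominator of the RPKM values is not stated. Every column matched the labels of 1 library. Each column was set against the window tracks by Pearson correlation of log2(value + 0.5) across 13817 genes, and the columns labelled KO input followed the KO IP tracks. For this reason transcript levels were also taken from the mean input coverage per gene, a measure added after the data were seen.

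Regions were runs of at least 2 consecutive windows of a gene with a winscore of at least 2 in the first IP, in genes with a mean RPKM of at least 1 over the WT and KO columns. The KO columns of this filter carry the doubt named above, and a filter on the WT columns only gave 10181 regions. The mean winscore of each region was compared between KO and WT with limma 3.58.1 (lmFit and eBayes with trend, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. Planning had assumed window counts for the test of IP against input. The files hold scaled coverage, so limma was run on log2((IP + 1)/(input + 1)) in regions with a mean input coverage of at least 1, after subtracting the library's median of this value outside regions (winscore under 1 in the first IP) over 5969 genes with a mean input coverage there of at least 5. Medians per library were compared by an exact two-sided permutation test.

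Transcript levels were tested with limma on log2(RPKM + 1) and on log2(coverage + 1), in genes with at least 1 in at least 2 of the 4 WT and KO inputs. Fold changes are on that scale, which understates the change of low genes. A gene list was tested with camera (limma) at a preset correlation of 0.01, with an estimated correlation as an alternative. The 16 lists were m6A writers, erasers and readers, naive pluripotency, primed and formative pluripotency, neural and ectoderm, mesoderm, endoderm, trophectoderm, two-cell-like, fibroblast, germ cell, interferon response, p53 targets and apoptosis, cytosolic ribosomal proteins, glycolysis, cholesterol synthesis, and chromatin regulators with Polycomb. Camera was also used to compare genes with and without regions. Lists among genes with regions were tested with Fisher's exact test against the other expressed genes (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Figures were drawn with matplotlib 3.10.9.

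The genes named were chosen by a fixed rule. Mettl3 came first. For transcript levels the rule took the 12 largest rises and 12 largest falls among genes past the test, with no overlap between WT and KO and a mean of at least 2 in a group. For regions, where fewer than 5 passed, it took the 8 with the smallest p in each direction, 1 region per gene, and said that they had not passed. It also took the 10 highest regions of the first IP in genes with a mean RPKM of at least 10. In each list up to 6 members with the smallest p could be named, and any member of the pluripotency and m6A lists. Some genes that the rule selects are not reported here. Imprinted genes of the closing observations were looked at after the data were seen. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

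The tests were tried on simulated data drawn from the real means and the moderated spreads that limma estimates, with 200 members changed. For region winscore 1.49, 20.9 and 92.4% of changes of 1, 2 and 4 (log2) were recovered among 11352 regions, and for the ratio of IP to input 2.99, 43.3 and 92.4% among 9925. For RPKM 0, 31.3 and 92.4% of changes of 0.5, 1 and 2 were recovered among 12245 genes, and for input coverage 98.5, 100 and 100% among 11211. In a simulation of lists of 20 genes in input coverage, camera called 20 of 20 lists raised by 0.3 and 0 of 80 unchanged lists. The simulated genes were drawn independently, so this does not show how camera behaves in lists whose genes vary together. Alternatives tried were region thresholds, filters, pseudocounts, scalings, other libraries for defining regions, a replicate block and leaving out each replicate. With a lone sample left in a group, limma assumes that it varies like the others. Sequence motifs and positions along transcripts were not analysed here.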

Results

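N6-methyladenosine (m6A) was mapped in the established mouse embryonic stem cell line J1 by immunoprecipitation (IP) of fragmented total RNA with an antibody against the modified base. Each IP library was paired with an input library of fragmented RNA that had not been precipitated. The series held 10 libraries. The first pair had no stated genotype. Another 2 pairs, whose titles name no genotype either, were taken as wild type (WT). The last 2 pairs came from cells in which Mettl3 had been knocked out (KO). Mettl3 encodes the methyltransferase that forms most m6A on messenger RNA. The comparison of KO with WT asked which m6A sites need Mettl3, and the input libraries gave transcript levels. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

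The files gave coverage in 1510223 exon windows of 30419 genes, not read counts. Coverage in every library moved in whole multiples of a small step, and total coverage divided by this step gave the depth of each library relative to the first library of its kind. The WT IP libraries had 0.159 and 0.0712 of the depth of the first IP, and the KO IP libraries had 0.0644 and 0.0606. Input depths were 0.438 and 0.457 of the first input in WT and 0.516 and 0.284 in KO. Windows without any IP signal made up 50.5 and 65.4% of all windows in WT and 74.3 and 67.6% in KO. The IP libraries of both genotypes were therefore shallow. KO replicate 1 had the most empty windows although KO replicate 2 was less deep, so depth alone does not order the libraries by empty windows.

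Mettl3 transcript was lower in the KO inputs and still present in both. Its mean input coverage was 4.79 and 4.67 in WT and 3.14 and 3.38 in KO, and 12.9 in the first input. It fell by 0.43 on the log2(coverage + 1) scale (n = 2 per group, limma adjusted p = 0.00259). The RPKM table listed 5.97 and 5.72 for the WT inputs, 2.00 and 2.26 for the columns labelled KO input, and 16.3 for the first input. Exon 8, as numbered in the window files, had a coverage of 0.388 in KO replicate 2 against 3.34 and 4.88 in WT and 3.33 in KO replicate 1. Exon 3 stood at 0.733 in KO replicate 2 against 3.91 and 2.58 in WT and 2.51 in KO replicate 1. The exon values were looked at after the data were seen. The labels do not say which part of the gene was altered, so the coverage that remained does not check the genotype.

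**Figure D1:**
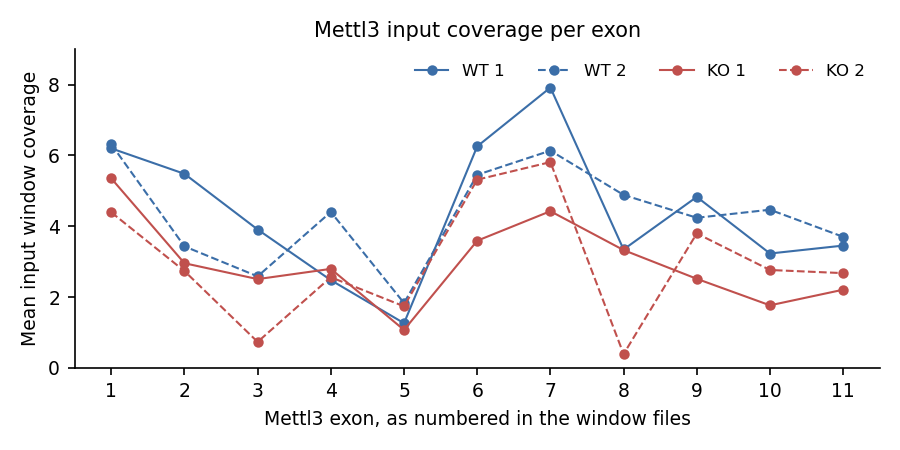
Mean input window coverage (authors' scaled coverage, y axis) of each Mettl3 exon as numbered in the window files (x axis), 1 line per WT (blue) or KO (red) input library. KO replicate 2 stands at 0.388 in exon 8, where the other 3 libraries lie between 3.33 and 4.88.

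Regions of m6A enrichment were taken from the first IP, which belongs to neither side of the KO comparison. A region was a run of windows whose winscore, the authors' log2 enrichment of IP over input within a gene, was at least 2. The first IP held 11352 such regions in 6834 of 12075 expressed genes (56.6%), with a median length of 4 windows. Genes counted as expressed by a mean RPKM of at least 1, which took in the columns labelled KO input. With this filter on the WT columns alone there were 10181 regions in 6136 of 11306 genes (54.3%). At a threshold of 1 or 3 there were 22238 and 6297 regions. Of the 6834 genes, 4057 had 1 region, 1701 had 2, 679 had 3 and 397 had 4 or more. Among genes with a mean RPKM of at least 10, the highest region winscores were 6.08 in Pak2, a p21-activated kinase, and 6.08 in Bag4. Values of 5.94 in Fam53c, 5.90 in Ddx6, an RNA helicase of processing bodies, and 5.81 in Herc2, a ubiquitin ligase, followed. Ppp2r5a (5.60), a regulatory subunit of protein phosphatase 2A, Zfp91 (5.55), Eda2r (5.49) and the noncoding transcripts guttman:linc1347.3 (6.07) and guttman:linc1587.3 (5.82) completed the highest 10. The mean RPKM took in the columns labelled KO input, and Fam53c, Herc2, Eda2r and guttman:linc1347.3, at 5.70, 3.19, 9.52 and 4.75 in the WT columns, reached 10 only through them. With 1 library there was no replicate of this map. Across its regions winscores of the first IP correlated at 0.486 and 0.436 with the WT IPs, against 0.799 between the WT IPs. Picking regions on the first IP can itself lower its correlations. Across genes the first input correlated at 0.763 and 0.762 with the WT inputs, which correlated at 0.997 with each other. The map may therefore differ from that of the cells compared.

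At a winscore threshold of 2, pluripotency genes carried regions more often than other expressed genes. In the naive pluripotency list 33 of 44 expressed members (75.0%) had a region, against 56.5% of other genes (adjusted p = 0.0382), among them Tet1 with 6 regions, Nr5a2 with 4, and Nanog and Sox2 with 2 each. In the list of primed and formative pluripotency 15 of 16 members had one (adjusted p = 0.00970), and among p53 targets and apoptosis genes 19 of 21 (adjusted p = 0.00970). Cytosolic ribosomal protein genes were at the other end, with 3 of 75 members (adjusted p = 1.24e-21), and their transcripts were short, with a median of 17 windows against 58 in other genes. Germ cell genes (2 of 12, adjusted p = 0.0273) and glycolysis genes (5 of 19, adjusted p = 0.0312) also had regions less often. These were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 16 lists, and 10 lists did not pass. Only the ribosomal list passed at every region threshold and background tried. With a winscore threshold of 1 or 3, or a background of RPKM at least 5, the number of lists that passed was 2, 1 and 2. Neither pluripotency list was among them, with adjusted p = 0.327, 0.803 and 0.0977 for naive and 0.217, 0.265 and 0.0977 for primed and formative genes. With the gene filter on the WT columns alone glycolysis did not pass (adjusted p = 0.0515), and 11 of 12 primed and formative genes had a region (adjusted p = 0.0272).

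Regions of the first IP remained enriched in the KO libraries. The median region winscore was 3.31 and 3.65 in the WT IP libraries and 3.50 and 3.33 in the KO IP libraries, a KO minus WT difference of −0.068 (exact permutation p = 1; the smallest p possible with 2 against 2 is 0.333). The sign of this difference was not stable. It was −0.24 without WT replicate 1, 0.11 without WT replicate 2, −0.15 without KO replicate 1 and 0.017 without KO replicate 2. After centring each library on windows outside regions both KO libraries lay below both WT libraries, at 3.25 and 3.14 against 3.26 and 3.48 (difference −0.17, exact permutation p = 0.333). With regions from the mean of 4 libraries the difference was 0.38 (exact permutation p = 0.667), but these regions were picked on the winscores then compared. With the highest window of each region of the first IP the difference was 0.18 (exact permutation p = 0.667). A winscore of at least 2 was held in both WT libraries by 9615 regions (84.7%) and in both KO libraries by 8235 (72.5%). Of the regions held in both WT libraries, 7741 (80.5%) were also held in both KO libraries. From WT replicate 1, 95.0% of regions were held in WT replicate 2, 85.1% in KO replicate 1 and 88.6% in KO replicate 2. From KO replicate 1, 89.8% were held in KO replicate 2 and 93.9 and 94.4% in the WT libraries, and from KO replicate 2, 86.6% were held in KO replicate 1. There were 72 regions at 2 or more in both WT libraries and under 1 in both KO libraries, and 4 with the opposite pattern. These shares carry no test, and they were not repeated with the gene filter on the WT columns alone.

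Measures that do not divide by the gene's own median were lower in KO. The IP signal in regions made up 47.6% ± 0.836 (SD, n = 2) of all IP signal in WT and 43.4% ± 0.188 (SD, n = 2) in KO (exact permutation p = 0.333), while the input share was 5.51% ± 0.0253 and 5.39% ± 0.154 (exact permutation p = 0.667). After scaling on windows outside regions, the median log2 ratio of IP to input over 9925 regions was 3.99 and 4.17 in WT and 3.60 and 3.71 in KO. The difference was −0.42 (exact permutation p = 0.333), and 7670 of the 9925 regions (77.3%) had a lower mean in KO. With the authors' scaling alone the difference was −0.35. The ratio was not repeated with the gene filter on the WT columns alone. Winscore, in contrast, divides by that median. Windows outside regions that reached a winscore of 2 made up 4.03 and 9.67% in WT and 13.6 and 11.1% in KO. Regions with a gene median IP signal of 0 made up 4.98 and 28.6% in WT and 53.9 and 35.4% in KO. Both shares rank the libraries alike, so the first cannot be read as more signal outside regions in KO.

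**Figure D2:**
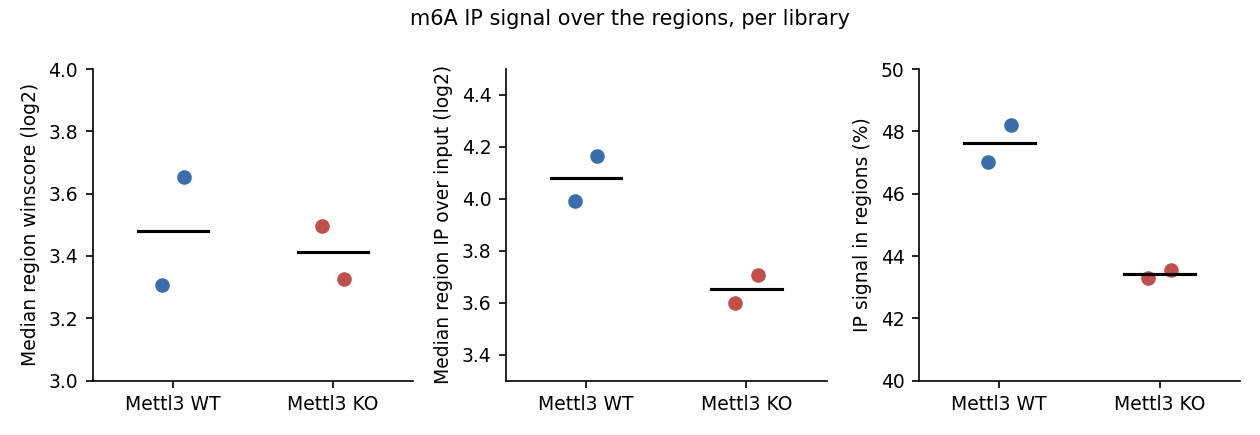
Values per IP library over regions of the first IP, in WT (blue) and KO (red). The panels give the median region winscore (log2), the median log2 ratio of IP to input scaled outside regions, and the percent of IP signal in regions; points are single libraries, lines are group means, and the y axes do not start at 0. The winscores of WT and KO overlap, and both other measures are lower in both KO libraries.

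No single region passed the unpaired test for a change between KO and WT. With limma, 0 of 11352 regions passed in winscore at an adjusted p of 0.05, and 943 had an unadjusted p under 0.05, of which 375 were higher and 568 lower in KO. This split turned with the highest window of each region (576 higher, 355 lower). It also turned with regions from the mean of 4 libraries (1889 and 396). Regions from the mean of the WT libraries gave 837 higher and 1202 lower. Both region sources used libraries under test, so neither gives a neutral direction. Winscore SDs outside regions were 1.07 and 1.38 in WT and 1.52 and 1.44 in KO. A highest window can grow with such spread. Without WT replicate 2 the median change per region was 0.087. In the ratio of IP to input 0 of 9925 regions passed, and 1591 had an unadjusted p under 0.05, of which 140 were higher and 1451 lower. Scaling the libraries on the regions themselves gave 595 and 544, but it removes any shift that most regions share. With the authors' scaling alone the split was 195 higher and 1256 lower. A replicate block or leaving out a KO library changed the number of regions that passed. With the block 15 regions passed in winscore (3 higher, 12 lower) and 0 in the ratio. Without KO replicate 1, 283 regions passed in winscore (77 higher, 206 lower) and without KO replicate 2, 1270 did (496 higher, 774 lower). For the ratio these counts were 654 and 2276, with 594 and 2042 of them lower. In simulated data with 5676 of the regions lowered, the winscore test recovered 1.22% of the lowered regions at a log2 fall of 1 and 67.8% at a fall of 2.

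The regions with the smallest p in each direction did not pass (limma adjusted p = 0.513 for each). Of these 16 regions, 8 passed with the replicate block, and the calls also changed when a KO library was left out. The regions were picked by p in the same libraries, so passing in another fit of those libraries is no independent support. On the lower side, a region in exon 8 of Gca, which encodes the calcium-binding protein grancalcin, had a mean winscore of 3.99 in WT and −0.50 in KO. The region in Taok1, a kinase of the STE20 family, had 4.77 and 0.63, that in Letmd1 had 4.21 and 0.31, and that in Aspa, which encodes aspartoacylase, had 3.79 and −0.61. Regions in Dgke, Slc12a9, Fzd3 and Dennd5b differed by −3.96, −3.63, −3.38 and −3.15. On the higher side, a region in Kpna4, a nuclear import receptor, had 3.35 in WT and 6.79 in KO, and that in Suox, which encodes sulfite oxidase, had 0.78 and 3.89. Regions in Esco1, Zfp711, Oxld1, Zfp420, Fbxl4 and Asl differed by 3.18, 2.94, 2.85, 2.81, 2.80 and 2.66. In the ratio of IP to input the regions of the lower side differed by between −4.56 (Aspa) and −2.94 (Dennd5b). Those of the higher side differed by only 0.37 (Oxld1) to 1.97 (Kpna4). The Zfp711 region, with a mean input coverage of 0.276, was too low for the ratio.

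No region of the gene lists passed. Over all regions 54.4% had a lower mean in KO in winscore and 77.3% in the ratio of IP to input, and no list was tested against these shares. The naive pluripotency genes held 55 regions in 33 genes, 34 of them lower in winscore and 46 of 55 lower in the ratio. The 2 regions of Nanog, a homeodomain factor of naive pluripotency, differed by −1.35 and −0.89 in winscore, with limma adjusted p = 0.605 and 0.680. The longer of the 2 Sox2 regions had 3.53 in WT and 3.58 in KO, and the region of Klf4 had 3.60 and 4.20. Cholesterol synthesis genes held 16 regions, 15 lower in winscore and 16 lower in the ratio. The m6A writers, erasers and readers held 41 regions, 25 of them lower in winscore, and 31 of 40 lower in the ratio. In the chromatin regulators 26 of 53 regions were lower in winscore and 36 of 52 in the ratio. More regions were higher than lower in winscore among p53 targets and apoptosis genes (12 of 26 lower) and interferon response genes (3 of 8 lower), while in the ratio 17 of 25 and 4 of 8 were lower.

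Transcript levels in KO and WT inputs differed in many genes. Mean input window coverage per gene was used for this comparison, a choice made after the data were seen, because the RPKM columns labelled KO input followed the KO IP tracks (described with the RPKM values). Of 11211 genes tested with limma, 1455 rose and 1522 fell in KO at an adjusted p of 0.05, and the WT and KO input tracks correlated across genes at r between 0.987 and 0.989 (genes are not independent replicates). Without the filter on low coverage 762 genes passed, with a minimum of 5 in place of 1 the count was 1930, and without WT replicate 1 or WT replicate 2 it was 1743 and 1930.

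The largest fall in KO was in Grb10, an adaptor of growth factor signalling whose gene is imprinted (read from the copy of a given parent), from 41.8 ± 1.02 to 6.29 ± 0.137 (mean coverage ± SD, n = 2; log2 change −2.55, SE 0.063, limma adjusted p = 3.30e-08). Cdkn1c, an imprinted inhibitor of the cell cycle, fell by 1.30 (adjusted p = 9.54e-06). Peg10, an imprinted gene derived from a retrotransposon, rose from 14.2 ± 0.768 to 48.5 ± 0.893 (log2 change 1.70, adjusted p = 1.26e-06). The imprinted genes Mcts2 and Nnat rose by 1.63 and 1.54. D7Ertd715e, an older name of the noncoding gene Snhg14 that spans the imprinted gene Snrpn, rose by 1.59, and guttman:linc1385.3 by 1.62. The last pair had equal coverage in 10 of 46 and 72 windows, so they are uncertain as separate genes. Tagln, an actin-binding protein of contractile cells, rose from 2.83 ± 0.483 to 11.4 ± 0.314 (log2 change 1.70, adjusted p = 4.75e-06). Anxa3, a membrane-binding annexin, rose by 1.62, Trh, the precursor of thyrotropin-releasing hormone, by 1.39, Car4, a carbonic anhydrase, by 1.36, and Thbs1, a secreted thrombospondin, by 1.35. Gm10664 rose by 1.35 as well. Among the other large falls were Jam2, a junctional adhesion molecule (−1.19), guttman:linc1246.3 (−1.18) and Mir3078 (−1.15), which was measured on a short transcript with WT values of 3.90 and 1.80.

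Naive pluripotency genes fell more often than they rose. Of 44 measured members 5 rose and 20 fell, with a median log2 change of −0.20 (camera adjusted p = 0.00485; adjusted p = 0.677 with an estimated correlation). Adjusted over the list alone, 10 rose and 23 fell. With a library left out between 1 and 5 rose and between 14 and 19 fell. Besides Jam2, the T-box factor Tbx3 fell from 24.3 ± 0.652 to 13.4 ± 0.785 (log2 change −0.81, limma adjusted p = 4.66e-05). Fbxo15 fell by 0.74, the growth factor gene Fgf4 by 0.60, the demethylase gene Tet2 by 0.57, the reprogramming factor Klf4 by 0.54 and Nanog by 0.35. Dppa3, a maternal factor that protects DNA methylation in the early embryo, went the other way and rose from 14.2 ± 1.96 to 45.4 ± 3.96 (log2 change 1.62, limma adjusted p = 8.13e-06). Pou5f1, which encodes OCT4, had 253 ± 9.50 and 250 ± 2.67 (log2 difference −0.018, limma adjusted p = 0.875), and Sox2 differed by −0.20 (limma adjusted p = 0.0594).

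Genes of the two-cell-like state, which mark a small fraction of cells in such cultures, fell. In this list 9 of 10 members fell and 0 rose, with a median of −1.19 (camera adjusted p = 9.59e-09; adjusted p = 0.548 with an estimated correlation), and the counts adjusted over the list alone were equal. The Zscan4 genes fell by between 1.14 in Zscan4d and 1.30 in Zscan4a, with Zscan4f at −1.29, Zscan4c at −1.24, Zscan4e at −1.24 and Zscan4b at −1.23. A7KBS4, which had equal coverage to Zscan4f in 22 of 39 windows, fell by 1.29. These genes are near-identical copies that can share reads, so their separate values are uncertain. Gm4340 fell by 0.85.

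**Figure D3:**
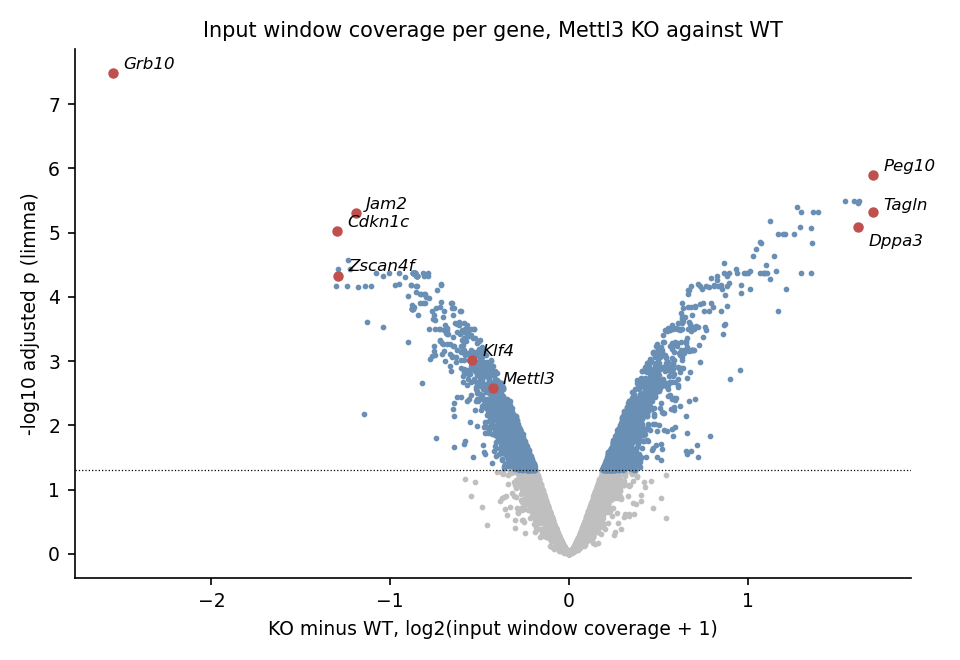
Change in mean input coverage per gene in KO against WT (x axis, log2 of coverage + 1) and −log10 of the limma adjusted p (y axis; dotted line, an adjusted p of 0.05; blue, genes past it), 1 point per gene of 11211 tested. Grb10 lies at −2.55 and Peg10 and Tagln at 1.70.

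Keratins of the trophectoderm list and contractile genes of the fibroblast list rose. In the trophectoderm list 3 of 7 members rose and 1 fell (camera adjusted p = 0.0134; adjusted p = 0.548 with an estimated correlation). The members that rose were the keratins of simple epithelia Krt8, from 3.63 ± 0.121 to 10.4 ± 0.0167 (log2 change 1.30, limma adjusted p = 4.75e-06), Krt18 (1.26) and Krt19 (1.01). The trophoblast factor Ascl2 fell by 0.32, and the trophectoderm factor Tfap2c had 22.9 and 23.7. The fibroblast list, included as the other cell type such a culture could hold, had 3 of 5 measured members higher and 0 lower (camera adjusted p = 0.0168; adjusted p = 0.548 with an estimated correlation). Tagln, Acta2, which encodes smooth muscle actin (limma adjusted p = 4.20e-05), and Twist1 (log2 change 0.45) rose, while fibronectin (Fn1) had 41.8 ± 1.01 and 42.5 ± 1.61 (log2 difference 0.022, limma adjusted p = 0.832) and Thy1 2.59 and 2.15. With a minimum coverage of 5 the fibroblast list no longer passed (camera adjusted p = 0.0851). Counts adjusted over the list alone were equal for both lists.

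Cholesterol synthesis genes rose, with 7 of 21 higher and 0 lower, also when adjusted over the list alone (median 0.14, camera adjusted p = 0.0110; adjusted p = 0.548 with an estimated correlation). Without WT replicate 1 only 2 were higher, and without KO replicate 2 only 4. Nsdhl rose by 0.68, the squalene epoxidase gene Sqle by 0.45 and Sc4mol by 0.29. Cytosolic ribosomal protein genes had 6 of 75 higher and 2 lower (median 0.12, camera adjusted p = 0.00238; adjusted p = 0.677 with an estimated correlation), and 1 and 0 adjusted over the list alone. This count rested on single libraries, with 23 higher and 2 lower without KO replicate 1 and 1 and 0 without WT replicate 2. Rpl29 rose by 0.33 and Rps24 fell by 0.27. The ribosomal list did not pass without WT replicate 2 (adjusted p = 0.0800), without KO replicate 2 (adjusted p = 0.110) or after quantile normalization (adjusted p = 0.166). With the fry test in place of camera the naive, two-cell-like, cholesterol and ribosomal lists did not pass (adjusted p = 0.111, 0.0577, 0.0709 and 0.177).

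The other 10 lists did not pass (camera). The m6A writers, erasers and readers had 4 of 30 members higher and 3 lower. In it Igf2bp2, an RNA-binding reader, rose by 0.42 and Zc3h13, a subunit of the writer complex, fell by 0.36, while Mettl14, the partner of Mettl3, had 7.80 ± 0.0491 and 8.16 ± 0.434 (limma adjusted p = 0.579). In primed and formative pluripotency 4 of 13 rose and 0 fell, led by Zic2 (0.73) and Pou3f1 (0.42). In the neural and ectoderm list 1 of 9 rose, the neural progenitor filament Nes (1.13), and 5 fell, among them Neurod1 (−0.66) and Sox1 (−0.55). In mesoderm 0 of 2 rose and 1 fell, Bmp4 (−0.47), and in endoderm 2 of 7 rose and 2 fell, with a median of −0.023 and a camera direction of up (adjusted p = 0.940). Germ cell genes had 2 of 11 higher and 5 lower, with Stra8, a gene of meiotic entry, at −1.04 (list adjusted p = 0.0838; without WT replicate 1 adjusted p = 0.0318). Interferon response genes had 4 of 10 higher and 2 lower, p53 targets and apoptosis genes 4 of 21 and 5, and glycolysis genes 2 of 19 and 3. Chromatin regulators had 0 of 28 higher and 8 lower, with Uhrf1, a cofactor of DNA methylation maintenance, at −0.45 (list adjusted p = 0.0750). The chromatin list passed without KO replicate 1 (adjusted p = 0.0163), without WT replicate 1 (adjusted p = 0.0328) and at a minimum coverage of 5 (adjusted p = 0.0105), but weakened to 2 lower without WT replicate 2 (adjusted p = 0.153) and to 1 higher and 4 lower without KO replicate 2 (adjusted p = 0.309). Adjusted over the list alone, the counts were 3 higher and 5 lower in germ cell, 5 and 3 in interferon response, 4 and 6 in p53 targets, 3 and 3 in glycolysis, and otherwise equal.

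No shift in the level of transcripts with m6A regions relative to those without was detected. The median log2 change in input coverage was −0.013 in 6086 genes with a region and 0.0095 in 5125 genes without, a difference of −0.023 (camera p = 0.422; p = 0.821 with an estimated correlation). Among genes with regions 708 rose and 803 fell, and among genes without regions 747 rose and 719 fell. The counts moved with single libraries, and among genes with regions they were 492 and 402 without WT replicate 2 and 311 and 487 without WT replicate 1. Matching genes on their number of windows turned the sign, with a difference of 0.022 that did not pass either.

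The RPKM table gave a different picture, and its columns labelled KO input did not behave as inputs. Across 13817 genes the first and WT input columns correlated with their own input tracks at r = 0.994, 0.995 and 0.995, and with their IP tracks at 0.808, 0.765 and 0.724. The columns labelled KO input correlated at 0.751 and 0.770 with the KO input tracks and at 0.960 and 0.976 with the KO IP tracks (correlations across genes, which are not independent replicates). Sox2 was listed at 166 and 179 in the WT columns and 1641 and 1859 in the KO columns, while its input coverage was 162 and 176 in WT and 148 and 145 in KO. Klf4 was listed at 72.9 and 76.1 in WT and 446 and 416 in KO, with input coverage of 68.1 and 70.9 in WT and 50.6 and 44.3 in KO.

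**Figure D4:**
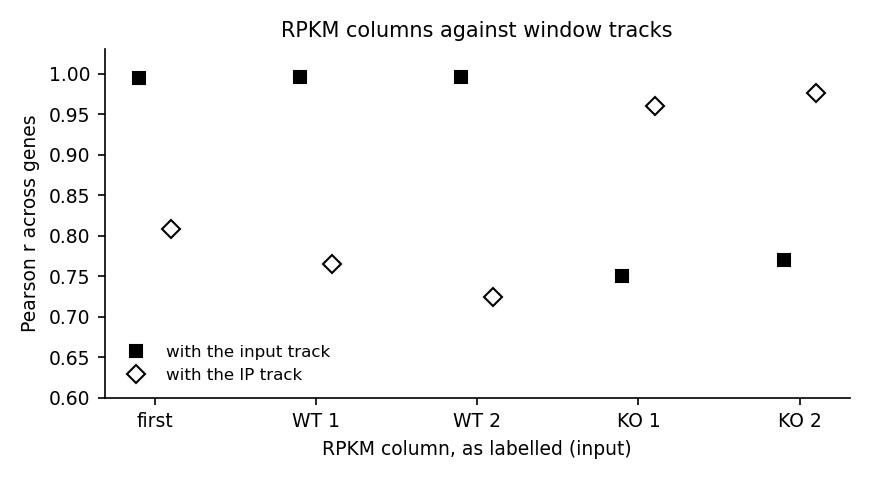
Pearson r across 13817 genes (y axis, from 0.6) between each RPKM column and the input track (squares) or IP track (diamonds) of the library pair it is labelled with (x axis). The columns labelled KO input lie at 0.751 and 0.770 with the input and 0.960 and 0.976 with the IP.

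The comparison planned on these columns is given as a description of the table and not as a change in transcript level. Of 12245 genes tested with limma, 5011 were higher and 2954 lower in the columns labelled KO input, and after quantile normalization 4260 were higher and 4053 lower. Without WT replicate 1 the total was 2273 and without WT replicate 2 it was 2333. Among the largest values on the higher side were uc007ajd.1 (log2 difference 5.58), uc009col.1 (5.12), Exosc6, a subunit of the RNA exosome (4.91), uc008dff.1 (4.82), 2010320M18Rik (4.63), Mocs3 (4.59), Mcts2 (4.49), NP_001170862 (4.48), Eid2 (4.41), Ptrh2 (4.32) and Cebpb (4.31). In input coverage Exosc6 differed by 0.13 (limma adjusted p = 0.182), Eid2 by 0.070 (0.482) and NP_001170862 by 0.023 (0.816). Mcts2 (1.63), Cebpb (0.55), 2010320M18Rik (0.51), Ptrh2 (0.30) and Mocs3 (0.26) also rose past the test in input coverage, by less than in the columns. Those on the lower side were Mir684-1.9 (−5.95), Snord65 (−5.87), Mir684-1 (−5.85), Mir5117 (−5.56), Snord110 (−5.19), Snord100 (−5.13), Snord96a (−5.06), Mir684-1.8 (−4.95), uc007pma.1 (−4.84), Mir684-1.4 (−4.83), uc007zbz.1 (−4.82) and Mir294 (−4.81). Snord65, Snord110, Snord100, Snord96a and Mir294 were listed at 0 in both columns labelled KO input, so their sizes rest on the pseudocount. In input coverage Mir294 (0.47), Mir684-1.4 (0.29) and Snord96a (0.22) rose past the test, and the others of the lower side did not pass.

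In the same table the ribosomal protein genes had 3 of 75 members higher and 66 lower (camera adjusted p = 7.90e-20; adjusted over the list alone, 3 and 68), glycolysis genes 2 of 19 and 11 (adjusted p = 0.0103), and germ cell genes 2 of 14 and 7 (adjusted p = 0.0371). Primed and formative pluripotency genes had 14 of 16 higher and 0 lower (adjusted p = 0.0128). The last 3 lists had equal counts adjusted over the list alone. With an estimated correlation the adjusted p was 0.892 for germ cell and 0.570 for the other 3 of these lists. The germ cell list also lost its call without KO replicate 1 (adjusted p = 0.186), after quantile normalization (adjusted p = 0.116) and at a minimum of 5 (adjusted p = 0.510), and the primed list at a minimum of 5 (adjusted p = 0.0601). Without WT replicate 1 the ribosomal list had 42 lower, glycolysis 5 lower and the primed list 4 higher. The other 12 lists did not pass, and in endoderm and cholesterol synthesis the camera direction was down while the medians were 0.13 and 0.13. Genes with m6A regions were higher than genes without by 1.53 (camera p = 1.09e-36, and p = 0.0138 with an estimated correlation). Regions were picked on IP enrichment, so columns that follow the IP tracks would give a higher value by construction.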

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

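The correlation of the RPKM columns with the tracks and the tests of a change in expression and of residual signal were chosen after the result was seen; the tests of genes listed at 0 and of gene medians were set out beforehand. The RPKM columns labelled KO input followed other tracks than their own: across genes they correlated with the KO IP tracks at r = 0.960 for replicate 1 and r = 0.976 for replicate 2. A change of expression in the knockout is argued against, since the KO input tracks, which should show it too, correlated with these columns at no more than 0.770. Values of the KO IP libraries in these columns are a candidate explanation: of the genes listed at 0, 95.3 and 94.3% had no signal in the KO IP track of that replicate, against 65.5 and 76.9% with none in its input track. The IP share alone does not set these columns apart, being 93.4 and 96.7% for the WT columns, while the input share there was 97.7 and 98.2%. How the columns came to hold such values was not tested.

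The median region winscore showed no stable fall in KO while the share of IP signal in regions fell, from 47.6 to 43.4%; centred on windows outside regions, the winscore was lower in both KO libraries, by 0.17. Winscore divides by the gene's median IP signal, which was 0 for 53.9 and 35.4% of regions in the KO libraries against 4.98 and 28.6% in WT. A part played by gene medians of 0 stays open: in regions of genes with a median above 0 in all 4 libraries the KO minus WT difference was −0.059 against −0.068 over all regions, but the SDs there were 0.172 and 0.223, and these genes were picked by the medians themselves. Signal of the antibody on unmodified RNA and m6A that remained in the KO cells cannot be told apart: 80.5% of regions held in both WT libraries were held in both KO libraries, and no library here lacks m6A by another means. A loss of m6A at the sites, the biological explanation the design names, stays open.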

How the results depend on the processing

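The coverage tests and the filter on WT columns were chosen after the data were seen. The number of regions was 22238 at a winscore of 1, 6297 at 3 and 7432 at a mean RPKM of 5. Region tests gave 0 calls under every threshold, filter, scaling and region source tried, except 184 in IP signal without the inputs (25 higher, 159 lower), the replicate block for winscore, and those with a library left out, which ranged from 0 to 1270 for winscore and from 0 to 2276 for the ratio. The median winscore difference was 0.38 with regions from the mean of 4 libraries, −0.17 when centred outside regions, and between −0.24 and 0.11 with a library left out. Regions held in both KO libraries numbered 5447 at a winscore of 3. The planned DESeq2 test was not run, since the files hold no counts.

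Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.010 for winscore, 0.0012 for the ratio, −0.031 for RPKM and −0.027 for coverage. With the replicate block 15 regions passed in winscore (3 higher, 12 lower) and 0 in the ratio, and 2737 genes in coverage and 7880 in RPKM.

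Genes passing in RPKM ranged from 2273 to 11086 with a library left out, and in coverage from 1743 to 3144; in coverage 762 passed without a filter, where more genes of low coverage entered, and 1930 at a minimum of 5. The number of lists that passed in RPKM was 4, against 0 with an estimated correlation, 14 with fry and 2 at a minimum of 5; in coverage it was 6, against 0 and 2 for the first pair. Lists among genes with regions numbered 2, 1 and 2 in place of 6. The difference between genes with and without regions in coverage reversed to 0.022 when matched on windows. Of 141 named coverage results, 78 lost the call without a filter, 6 with the block and between 20 and 42 without a library. Without a library Pou5f1 lay between −0.056 and 0.020 and Fn1 between −0.016 and 0.060; Pou5f1 reversed to 0.020 without WT replicate 2, and Fn1 to −0.0024 without WT replicate 2 and to −0.016 without KO replicate 1. For these changes the cause was not tested.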

Other observations

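Imprinted genes beyond those already named were read in the inputs with 3 lists written after the first of them had been seen; the test of separate loci was chosen after the result was seen, and that on genes not yet looked at was set out beforehand. Plagl1, an imprinted zinc finger factor read from the paternal copy, rose from 0.030 ± 0.031 to 1.65 ± 0.094 in input coverage (mean ± SD, n = 2; log2 change 1.36, limma adjusted p = 1.43e-05). Sgce, the neighbour of Peg10, rose by 1.11, Snurf and Snrpn, which had equal coverage in 28 windows, by 1.21 and 1.20, Ndn by 0.71 and Zrsr1 by 0.48. Phlda2, a growth-restraining gene read from the maternal copy, fell by 0.41, and Peg3, read from the paternal copy, fell by 0.21. Mest, Impact and Igf2r did not pass (limma adjusted p = 0.859, 0.216 and 0.184). At the loci whose control region is methylated on the paternal copy, Igf2 rose by 0.60 and H19 fell by 0.41, while Rian rose by 0.50, Meg3 by 0.37 and Mirg by 0.49, and Dio3 fell by 0.62.

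A hypothesis for these changes is a loss of maternal methylation imprints in the KO cells, which would raise genes read from the paternal copy and lower those read from the maternal copy of such loci. Of 18 genes past the test at such loci 15 went that way, but 9 of them had been seen first. Of 14 tested genes not seen beforehand 9 passed, and 6 of these 9 (66.7%) went that way. This share lay between the bounds of 60 and 80% set for rejecting or keeping the hypothesis. Of these 6, 4 lay at loci where a gene had been seen first, and at loci not seen before 2 of 4 did, so the test leaves the hypothesis open. Genes past the test lay at 10 separate loci, so a single pair of overlapping genes that share reads does not account for all. In coverage 1455 genes rose and 1522 fell among 11211, so several loci could pass in any such list. The number of loci therefore says little more on shared reads as a cause. The 9 of 14 genes not seen beforehand were a larger share than over all genes, but some lay at loci seen first and the share was not tested. No prediction covered the loci methylated on the paternal copy, where genes also passed. Clonal differences between the cultures, which could give such a pattern without any role of Mettl3, were not tested.

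The first input stood apart from the other inputs, with correlations across genes between 0.755 and 0.764 against all 4, while WT and KO inputs correlated at 0.987 to 0.989.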
